A study of Homo sapiens with 4 samples.

How the data were processed

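Total RNA of the human myeloma cell line H929 was labelled with biotin using a whole-transcript kit and hybridised to arrays, per the labels' protocols, with 2 untreated samples and 2 samples given meayamicin B at 3 nM over 8 h. The authors summarised each array with RMA and used Transcriptome Analysis Console, with genome build hg38, per the submitters' processing notes, and no versions are given in the sources used here. The deposited values are log2 expression, 1 value per row and array, which was read from their range and from the named RMA method. RMA subtracts background, equalises the distributions of the arrays and summarises probes, so a shift of all RNA in treated cells would be removed, and dim rows are compressed toward the floor. Which arrays were normalized together is not given in the sources used here. The number of arrays, 2 per group, limits the precision. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

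Groups were taken from the treatment label and replicate numbers from the title. Of 138745 rows, 2995 control rows were left out, among them 612 negative controls, 155 ERCC rows and 31 background and spike-in rows. Rows were named through the platform annotation, with symbols updated through a RefSeq gene table of GRCh38.p14, which also gave the printed coordinates and is the build named by the submitters. Of the 135750 rows tested, 36176 carried 1 gene symbol, 1119 several and 98455 none, and 25516 of the single-symbol rows matched the RefSeq table. No gene was named from a row with several symbols, except that the differences of the rows naming ZFAS1 or LMNB2 with other genes are given beside those genes. Each of 33616 genes was represented by its row with the highest mean over the 4 arrays, 1576 genes had more than 1 row, and 2 genes had rows called in opposite directions in the trended fit. A gene was above background in a group when both arrays exceeded the 95th percentile of their own negative control rows. Where no array of the dimmer group exceeded it, the fold is given as a bound: the brighter group's mean against the mean over the dimmer group's arrays of the higher of the background and the measured value.

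Meayamicin B was compared with untreated by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with defaults), with Benjamini-Hochberg adjustment over all rows tested and a threshold of 0.05. With 2 residual degrees of freedom, the default prior added 5.12. The same fit with an intensity-dependent and robust prior, planned as an alternative, was adopted as a second count after the data had been examined, because it called many more genes. It is called the trended fit. Printed SEs and confidence intervals come from the default fit, also beside genes called in the trended fit. For gene lists, p-values were also adjusted over the list alone. The lists were written before the data were examined, 26 of 27 had at least 4 measured genes, and they were tested with limma's camera with a preset correlation of 0.01, adjusted over the 26 lists. With an estimated correlation 0 of the lists passed. Limma's fry, which tests whether a list's genes move on balance in a single direction and does not compare them with other genes, was an alternative. The 6 lists of markers of other cell types were adjusted among themselves. Named genes were chosen by a rule fixed before the data were examined: up to 10 highest and 10 lowest log2 fold changes among genes past the threshold whose groups did not overlap and whose higher mean reached the median of 4.18 over genes, all BCL2 family members, up to 2 highest and 2 lowest members of each list by moderated t, and 3 highest and 3 lowest noncoding genes. The rule was applied to the default fit and again to the trended fit, and the members with the smallest differences in lists that did not pass are not all printed. Other list members past a threshold, SF3B1 and IRF4, NDUFS6 and MIPEP as parents of pseudogenes, and the genes in the closing observations were named after their values were seen. BBC3 had no single-gene row. Of 24298 genes with a chromosome in the RefSeq table, 13 were represented by a row whose identifier names another chromosome. Of these 1 was called in the trended fit, MIR548AI, which the rule took as a noncoding gene and which is not given because its row may not measure it.

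The replicate numbers are shared by both groups. Deviations of same-numbered arrays from their group means correlated at r = 0.02 over all rows and 0.10 over genes above background. The labels do not say that the number marks a batch, so the fit without a replicate block was used. The alternatives were a replicate block, the trended prior, a filter on dim rows, a second quantile normalization, centring on ribosomal protein genes, leaving out each array, a 2-fold minimum, and the mean of all rows of a gene. Quantile normalization moved the median log2 fold change of genes above background from -0.09 to -0.03.

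The tests were tried on simulated data with the real rows' means. The spreads were drawn from the prior of the trended fit, which favours that fit in the comparison below. Changes were placed only in brighter rows, so detection in dim rows was not tried. With the default prior, 0% of rows changed 2-fold, 40% of rows changed 4-fold and 98% of rows changed 8-fold were called, over 50 rows of each size among 135750. With the trended prior these were 16%, 90% and 98%. With nothing changed, 0 rows were called in either fit. Camera called 100% of 25 simulated lists shifted by 0.5 and 0% of 100 unshifted lists. The simulated genes were independent, so this does not show how often camera with a preset correlation calls unshifted lists of correlated genes. Permutation tests used 100000 resamples and were two-sided, with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Splice junctions and exons were not analysed here, since the rows are gene-level summaries.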

Results

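Gene expression was measured on whole-transcript arrays in H929, an established human multiple myeloma cell line, with and without meayamicin B. Meayamicin B is a synthetic small molecule that binds the SF3B complex of the U2 snRNP, which recognises the branch site of introns, and inhibits splicing of pre-mRNA. Total RNA came from 2 untreated samples and from 2 samples exposed to 3 nM meayamicin B for 8 h, each hybridised to its own array. The deposited log2 values had array medians between 3.03 and 3.08 over 138745 rows, and with 2 arrays per group their number limits the precision. The 95th percentile of 612 negative control rows, used as the background, was 4.50 and 4.76 in the untreated arrays and 5.03 and 5.13 in the treated arrays. Of 33616 named genes, 14296 lay above it in both arrays of at least 1 group. Across the 135750 rows tested, which are not independent replicates, Pearson's r was 0.984 within the untreated pair, 0.981 within the treated pair and 0.975 to 0.980 between arrays of different groups. The poly-A control RNAs dap, phe and thr were above background in the replicate 1 arrays of both groups and below it in the replicate 2 arrays, so differences within each replicate number are given beside the group difference for the leading results.

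The first question was which transcripts differed after 8 h of meayamicin B. NPR3, which encodes the natriuretic peptide clearance receptor, rose 9.09-fold, from 4.64 ± 0.03 to 7.82 ± 0.15 on the log2 scale (SD, n = 2 arrays per group), and lies on chromosome 5 at 32690872 to 32791720 (GRCh38). Its log2 fold change was 3.18 (SE 0.19, limma adjusted p = 0.0258), with 3.31 in the replicate 1 pair and 3.06 in the replicate 2 pair, and it was above background in 1 of the 2 untreated arrays. ZFAS1, a noncoding host gene of small nucleolar RNAs, rose 10.6-fold on its single-gene row, from 5.42 to 8.82 (log2 fold change 3.40, SE 0.28, limma adjusted p = 0.0397). A separate, brighter row that names ZFAS1 with 3 other genes was at 10.31 untreated and 10.37 treated, a difference of 0.07 (SE 0.18). LMNB2, the gene of lamin B2, rose by 2.75 (SE 0.22) on its single-gene row, from 4.65 to 7.40, where 1 of the 2 untreated arrays was above background. A brighter row that LMNB2 shares with 1 other gene was at 7.14 untreated and 7.16 treated, a difference of 0.03 (SE 0.19). Among genes that fell, CLUAP1, an intraflagellar transport gene, had a log2 fold change of -2.42 (SE 0.19) and TMEM131L -2.35 (SE 0.19), both with a limma adjusted p of 0.0397. CLUAP1 was at least 2.19-fold lower and TMEM131L at least 2.20-fold lower, since neither was above background in a treated array.

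In limma's test with its default prior, 22 of 135750 rows passed an adjusted p under 0.05, 16 higher and 6 lower, and 12789 rows had an unadjusted p under 0.05. These rows held 11 named genes, 8 higher and 3 lower. Besides those above, the pseudogenes MTND2P12 (log2 fold change 3.60, at least 5.62-fold), MTND1P14 (3.38, 10.4-fold, above background in 1 of the 2 untreated arrays), NDUFS6P1 (2.46, at least 4.19-fold) and MIPEPP1 (2.14, at least 1.42-fold) rose, as did CMYA5 (2.91, at least 1.55-fold, above background in 1 of the 2 treated arrays), a gene of striated muscle. The row identifiers of MTND2P12 and MTND1P14 name the same chromosome and are close in number, so these genes may not be independent. With the replicate number as a block, MIPEPP1 had a limma adjusted p of 0.0507. The antisense RNA ELOA-AS1 fell by 2.69 on the log2 scale and was at least 1.67-fold lower. NDUFS6, the parent gene of NDUFS6P1, differed by 0.28 (SE 0.20) and MIPEP, the parent of MIPEPP1, by 0.19 (SE 0.31), neither past the threshold. MIPEP was below background in both treated arrays and above it in 1 of the 2 untreated arrays, so its row cannot show whether it changed. Centring the arrays on ribosomal protein genes gave 19 genes, 11 higher and 8 lower. Leaving out an array leaves 1 residual degree of freedom, and limma then called 0 genes, while the fold changes of NPR3 stayed between 3.08 and 3.29 and those of CLUAP1 between -2.50 and -2.34.

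A fit in which the prior variance followed the signal level called far more genes. It was adopted as a second count after the data had been examined, and it called 1059 of 33616 genes, 117 higher and 942 lower, including 577 that changed at least 2-fold. Of 945 protein-coding genes called above background, 874 fell, or 92.5%. Genes that fell besides those named included IGF2BP3, an mRNA-binding protein (4.66-fold lower, log2 fold change -2.22, SE 0.23), PHF19, a Polycomb-associated factor (4.38-fold lower, with a dimmer second row at -0.11), ZWILCH, a kinetochore protein (4.14-fold lower, above background in 1 of the 2 treated arrays), and PAAF1, a proteasome assembly factor (4.08-fold lower). The kinase gene ROCK2 was at least 2.51-fold lower, the ciliary gene CEP290 at least 2.32-fold lower and the pseudouridine synthase gene PUS10 at least 1.91-fold lower. AFG1L was at -2.09 and had no usable fold, because its untreated level lay under the background of the treated arrays. OVGP1, an oviductal glycoprotein gene (5.55-fold higher, log2 fold change 2.47, above background in 1 of the 2 untreated arrays), TECTA, which encodes a protein of the inner ear (5.27-fold higher, 2.40), and ERMN, a gene of oligodendrocytes (at least 2.26-fold higher, 2.20), rose. The limma adjusted p values of these 3 genes in the trended fit lay between 0.00139 and 0.00532. Among noncoding genes, MIR579 (2.42, above background in 1 of the 2 untreated arrays), RNU6-1079P (1.92) and SNORD19 (1.68) rose, while ASB16-AS1 (-2.06, at least 3.67-fold lower) fell. The row identifiers of MIR579 and RNU6-1079P name the same chromosome and are close in number. The trended count was 394 without untreated replicate 1, 276 without untreated replicate 2 and 518 without treated replicate 2, and it was 2168 with the replicate number as a block.

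**Figure D1:**
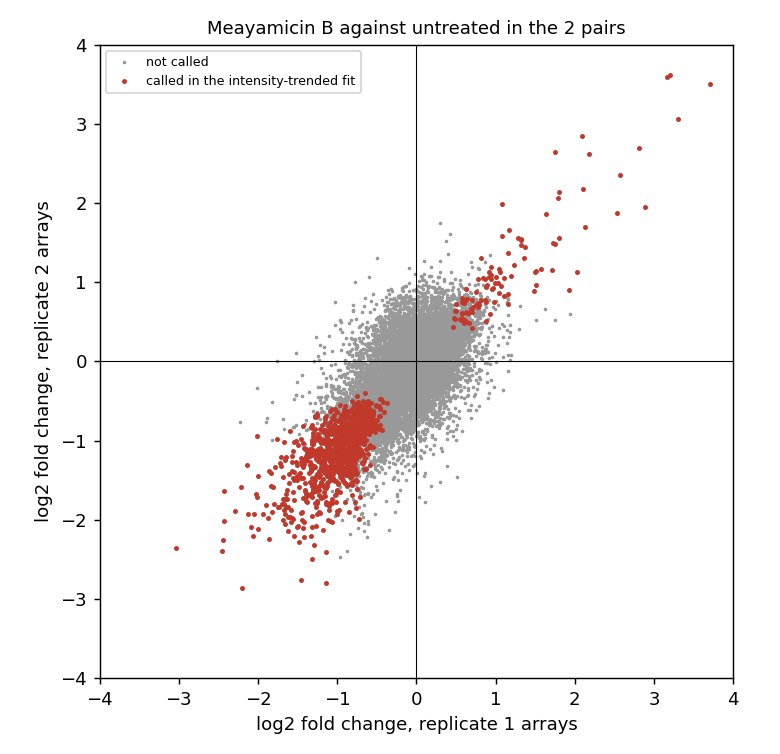
Log2 fold change of 14296 genes above background, meayamicin B minus untreated, in the replicate 1 arrays (horizontal) and the replicate 2 arrays (vertical), with genes called in the intensity-trended fit in red. The 2 pairs correlated across genes at r = 0.69, and 72.3% of genes had the same sign in both.

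Across the 14296 genes above background, which are not independent replicates, the fold changes of the replicate 1 and replicate 2 pairs correlated at r = 0.69, and at r = 0.63 with the pairs crossed. Protein-coding genes above background had a median log2 fold change of -0.15 over 10299 genes and long noncoding RNA genes -0.14 over 419. The corresponding medians were 0.15 for 77 small nucleolar RNA genes, of which 5 rose and 0 fell in the trended fit, and 0.18 for 339 microRNA genes, of which 6 rose and 1 fell, the last on a row whose identifier names another chromosome than the gene table. The median of 39 small nuclear RNA genes was 0.23, with 0 called in the trended fit by limma and 27 higher in both pairs. The 2 treated arrays carried the higher negative controls, at 5.03 and 5.13.

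The series title frames the treatment around dependence on BCL2 and the BCL2 inhibitor venetoclax, so the BCL2 family was examined next. BCL2A1, an antiapoptotic member on chromosome 15 at 79960892 to 79971196, was 2.38-fold lower, with 6.62 ± 0.06 untreated and 5.37 ± 0.07 after meayamicin B (SD, n = 2 arrays per group). Its log2 fold change was -1.25 (SE 0.19), with -1.24 and -1.25 in the replicate 1 and replicate 2 pairs. It fell when adjusted over the list alone of 15 measured family members (limma adjusted p = 0.00374), but not over all rows (limma adjusted p = 0.0995), and it also fell over all rows in the trended fit (limma adjusted p = 0.0172). MCL1, an antiapoptotic member, was at 11.71 ± 0.03 untreated and 11.53 ± 0.05 treated, a log2 difference of -0.17 with a 95% confidence interval of -0.61 to 0.26.

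BCL2, on chromosome 18 at 63123346 to 63320090, had a log2 difference of 0.60 (95% confidence interval 0.04 to 1.15, limma adjusted p = 0.497), with 6.07 ± 0.10 untreated and 6.67 ± 0.39 treated (SD). The difference was 0.39 in the replicate 1 pair and 0.80 in the replicate 2 pair, and it was 0.32 without treated replicate 2 and 0.87 without treated replicate 1. BCL2L1, the gene of BCL-xL, had a difference of 0.55 (95% confidence interval 0.11 to 0.98, limma adjusted p = 0.403 over all rows and 0.150 over the 15 family members). Its p adjusted over the list alone of the 5 antiapoptotic genes was 0.04998 in limma, just under the threshold, and it passed over the 15 family members in the trended fit (limma adjusted p = 0.0450). BCL2L2 was at -0.06 (SE 0.23), with -0.40 and 0.28 in the 2 pairs. Of the 10 proapoptotic genes measured, 0 passed over all rows and 0 when adjusted over the list alone in limma, and 0 in the trended fit. Those with positive differences were BAX (0.40, SE 0.23), BMF (0.40, SE 0.20), PMAIP1 (0.34, SE 0.19, below background in both treated arrays), HRK (0.15, SE 0.25) and BIK (0.13, SE 0.21). The other 5 were BID (-0.30, SE 0.19), BCL2L11, the gene of BIM (-0.27, SE 0.19), BAD (-0.25, SE 0.19), BOK (-0.22, SE 0.31, above background in 1 of the 2 treated arrays) and BAK1 (-0.20, SE 0.18). Over the whole family, 0 of 15 genes passed over all rows and 1 when adjusted over the list alone, and 3 had an unadjusted limma p under 0.05. The limma camera test gave adjusted p = 0.971 for the antiapoptotic list and 0.795 for the proapoptotic list, both toward higher values although their medians were -0.06 and -0.03. Each value summarises a whole gene, so isoforms of BCL2L1, MCL1 or BCL2L11 were not told apart.

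**Figure D2:**
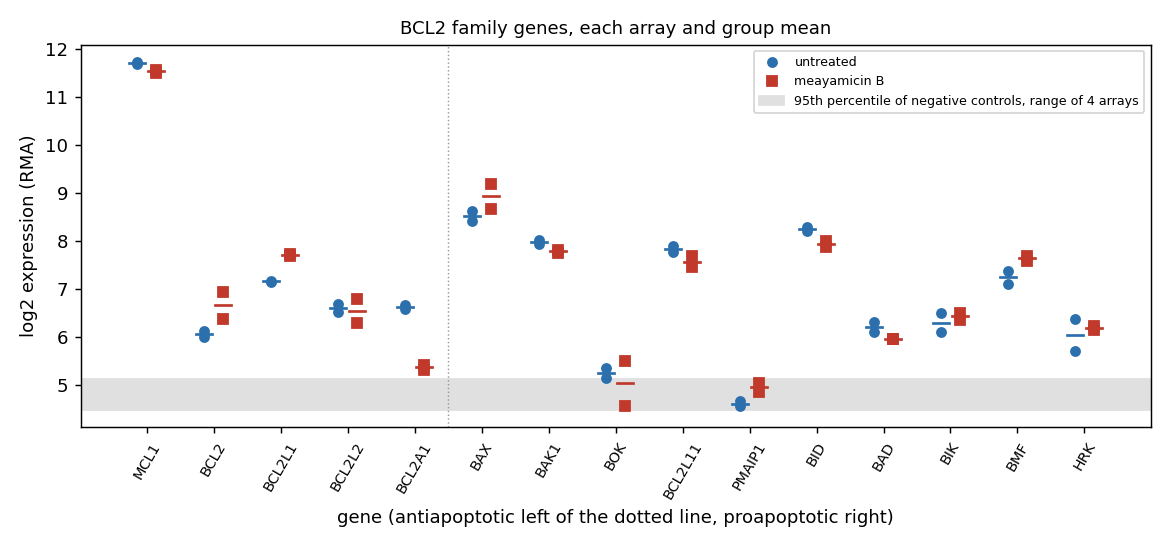
Log2 expression of 15 BCL2 family genes in each array, untreated (blue circles) and meayamicin B (red squares), with horizontal bars at the group means and the range of the negative control 95th percentile in grey. BCL2A1 lies at 6.62 untreated and 5.37 treated, and MCL1 at 11.71 and 11.53.

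Genes were then compared in groups fixed beforehand. DNA replication genes fell as a list in limma camera (adjusted p = 2.2e-10, and adjusted p = 0.263 with an estimated correlation), with a fry adjusted p of 0.0160. The 29 measured members had a median log2 fold change of -0.59, and 27 were lower in both pairs. The largest falls were in GINS1, a subunit of the replicative helicase (2.90-fold lower, log2 fold change -1.54, SE 0.19), and CDC45, its partner in that helicase (2.69-fold lower, -1.43, SE 0.21). PCNA, the sliding clamp of DNA polymerase, was at -1.23 (SE 0.20), and CDC6, a licensing factor, at -1.19 (SE 0.18). Adjusted over the list alone, 14 genes fell and 0 rose, against 0 over all rows and 11 in the trended fit. CCNE1 (0.07, SE 0.19) and CDT1 (0.09, SE 0.20) had the highest values. The medians were -0.44 in the replicate 1 pair and -0.66 in the replicate 2 pair.

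Replication-dependent histone genes, which lack introns and are transcribed in S phase, had a median of -0.42 over 36 measured members, of which 36 were below 0 and 32 lower in both pairs. H1-3 (-1.02, SE 0.20) and H3C10 (-1.04, SE 0.22, at least 1.501-fold lower and below background in both treated arrays) fell when adjusted over the list alone, against 0 genes over all rows. In the trended fit 2 genes were lower, H1-3 and H1-4 (-0.52), while H3C10 did not pass (limma adjusted p = 0.0897). The list fell in limma camera (adjusted p = 3.3e-08, and adjusted p = 0.263 with an estimated correlation), with a fry adjusted p of 0.0418. The medians of the 2 pairs were -0.38 and -0.39. Genes of homologous recombination and interstrand crosslink repair had a median of -0.67 over 19 members, with 9 lower and 0 higher when adjusted over the list alone, against 0 over all rows and 4 lower in the trended fit (BRCA1, RAD51C, XRCC2 and MRE11). Among the 9, BRCA1 was at -1.09 (SE 0.22), FANCL at -1.02 (SE 0.22, above background in 1 of the 2 treated arrays), RAD51C at -0.94 (SE 0.21) and MRE11 at -0.70 (SE 0.19). PALB2 was at 0.44 (SE 0.19) and FANCF at 0.28 (SE 0.19), neither past a threshold. The limma camera test gave adjusted p = 0.000357, and adjusted p = 0.481 with an estimated correlation. The fry adjusted p was 0.134 in limma, with medians of -0.53 and -0.69 in the 2 pairs.

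Targets of p53 rose as a list in limma camera (adjusted p = 4.4e-05, and adjusted p = 0.325 with an estimated correlation), while the fry adjusted p was 0.0809. Their median was 0.40 over 22 members, of which 16 were higher in both pairs. SESN1, a stress-response regulator of TORC1 (1.93-fold higher, log2 fold change 0.95, SE 0.19), GADD45A, a DNA damage response gene (1.87-fold higher, 0.90, SE 0.20), and TP53INP1 (1.78-fold higher, 0.83, SE 0.21) passed when adjusted over the list alone. Over all rows 0 of the 22 passed in limma, and 2, SESN1 and GADD45A, rose in the trended fit. DDB2 (-0.52, SE 0.20) and XPC (-0.54, SE 0.25), both nucleotide excision repair genes, lay at the other end. The medians were 0.30 and 0.54 in the 2 pairs. KRAB zinc finger genes, which encode DNA-binding repressors, had a median of 0.30 over 43 members, of which 26 lay above background. The highest by moderated t were ZNF12 (0.87, SE 0.23) and ZNF227 (0.68, SE 0.19), and the lowest were ZNF100 (-0.69, SE 0.23) and ZNF25 (-1.32, SE 0.41), which was below background in both treated arrays and had no usable fold, with 0 genes past the threshold over all rows or when adjusted over the list alone. This list rose in limma camera (adjusted p = 0.000203, and adjusted p = 0.434 with an estimated correlation), while the fry adjusted p was 0.159. Its median was 0.16 without untreated replicate 2, and 0.15 and 0.33 in the 2 pairs. Markers of monocytes moved the same way as these lists that rose, with a median of 0.48 over 8 genes of which 2 lay above background.

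**Figure D3:**
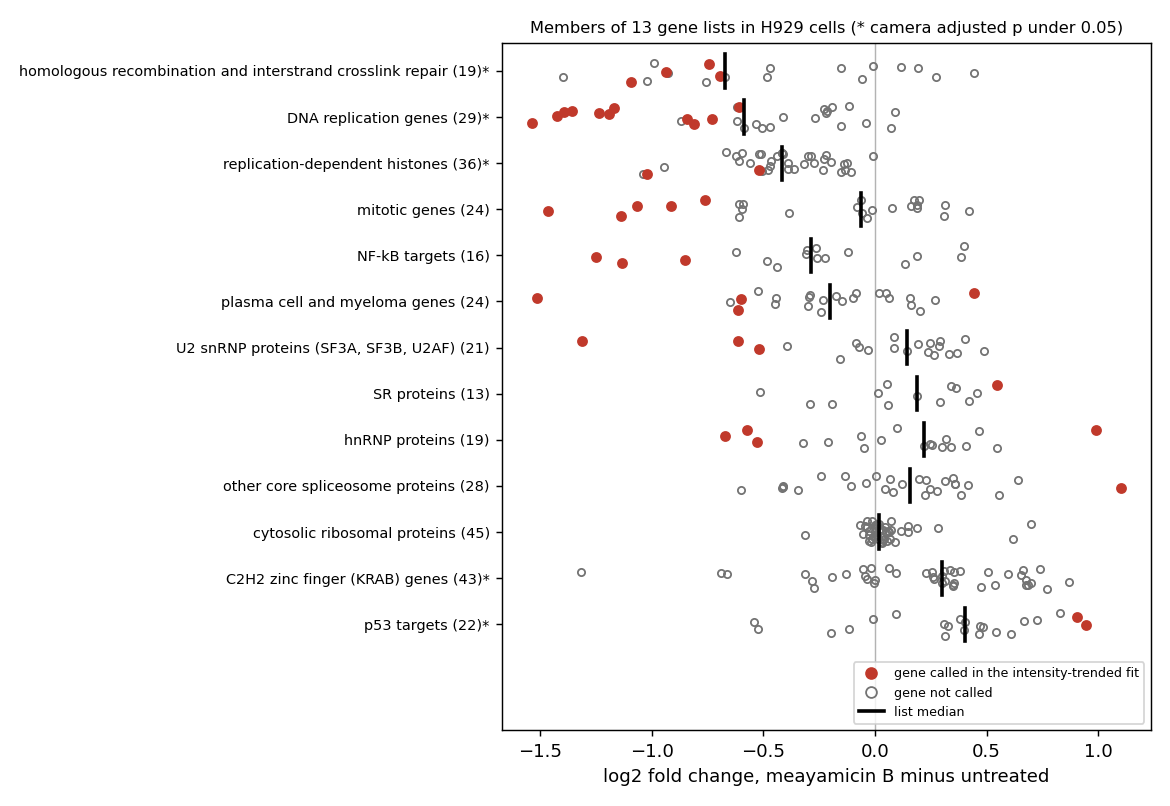
Log2 fold change, meayamicin B minus untreated, of each measured member of 13 gene lists, with the list median as a black bar, members called in the intensity-trended fit in red and the number measured in parentheses. Lists marked with an asterisk passed limma camera with a preset correlation, with medians of -0.67, -0.59, -0.42, 0.30 and 0.40, and 0 of them passed with an estimated correlation.

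Components of the splicing machinery, the target of the compound, were measured at gene level. U2SURP, a protein associated with the U2 snRNP, was 2.48-fold lower (log2 fold change -1.31, SE 0.20) and fell when adjusted over the list alone of 21 U2 snRNP genes (limma adjusted p = 0.0064). SF3B1, the subunit that meayamicin B contacts, was at 0.33 (SE 0.20, limma adjusted p = 0.678) on 1 row and 0.06 on a dimmer row. In the trended fit SF3A3 (-0.61) and SNRPA1 (-0.52) fell as well, whereas PHF5A was at 0.49 (SE 0.18) and SNRPB2 at 0.40 (SE 0.19). PRPF3, a protein of the U4/U6 snRNP, rose 2.15-fold (1.10, SE 0.18) and HNRNPDL, an RNA-binding protein, rose 1.99-fold (0.99, SE 0.18), each adjusted over the list alone. In the trended fit the hnRNP genes HNRNPAB (-0.67), HNRNPM (-0.58) and HNRNPU (-0.53) fell, and the SR protein gene SRSF4 (0.55) rose. The median was 0.14 for the 21 U2 snRNP genes, 0.19 for 13 SR protein genes, 0.22 for 19 hnRNP genes and 0.16 for 28 other spliceosome genes. None of these lists passed limma camera, with adjusted p values of 0.421, 0.0943, 0.156 and 0.0657. Nonsense-mediated decay factors had a median of -0.12 over 10 genes (limma camera adjusted p = 0.849), and 0 members passed in either fit. Intronless genes other than histones had a median of 0.11 over 24 genes (limma camera adjusted p = 0.102, fry adjusted p = 0.0418), and TAF7 (0.54) rose in the trended fit. Of the snoRNA host list 2 genes had a row of their own, ZFAS1 and EPB41L4A-AS1 (-0.27, SE 0.18), so that list was not tested.

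Plasma cell and signalling genes were mixed. SLAMF7, the surface antigen targeted by elotuzumab, was 2.86-fold lower (log2 fold change -1.52, SE 0.22) and fell when adjusted over the list alone of 24 plasma cell and myeloma genes (limma adjusted p = 0.00518). In the trended fit PIM2, a kinase gene (-0.61), and POU2AF1, a B-lineage coactivator (-0.60, with a dimmer second row at 0.03), fell and PRDM1, which encodes the plasma cell regulator BLIMP1 (0.45), rose, while MYC was at 0.27 (SE 0.19) and IRF4 at 0.16 (SE 0.19). The list had a median of -0.20, a limma camera adjusted p of 0.0943 and a fry adjusted p of 0.0418 toward lower values. Among 16 NF-kB targets, NFKB2 (-1.14, SE 0.18), BCL2A1 and CFLAR, an inhibitor of caspase-8 (-0.85, SE 0.19), fell when adjusted over the list alone and in the trended fit, and TNFAIP3 was at 0.40 (SE 0.19). The list median was -0.29, with limma camera adjusted p = 0.0623, and 0.0460 with the replicate number as a block, and a fry adjusted p of 0.0418. Of 24 mitotic genes, 5 fell when adjusted over the list alone, against 0 over all rows and 5 in the trended fit: HMMR (-1.46, SE 0.21), the kinesin gene CENPE (-1.14, SE 0.19), TOP2A (-1.07, SE 0.21), CDC20 (-0.91, SE 0.18) and AURKA (-0.76, SE 0.19). CENPF (0.42, SE 0.19) and BIRC5 (0.31, SE 0.19) had the highest values, the median was -0.06 and the limma camera adjusted p was 0.0943.

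Stress response genes showed single members past the threshold, and none of their lists passed limma camera. MANF, a chaperone-like factor of the endoplasmic reticulum (-0.92, SE 0.19), fell when adjusted over the list alone of 18 unfolded protein response genes, whose median was 0.01 although limma camera pointed to lower values (adjusted p = 0.680). STIP1 (-0.79, SE 0.19) and HSPH1 (-0.70, SE 0.18), a cochaperone and a chaperone of the heat shock response, fell adjusted over the list alone of 13 genes with a median of -0.12 (limma camera adjusted p = 0.102). The heat shock list was also the stress list that passed limma's fry, toward lower values (adjusted p = 0.0418). In the amino acid response list of 14 genes, STC2 rose (1.00, SE 0.21) when adjusted over the list alone, and VLDLR (-1.03, SE 0.22) passed as lower but had no usable fold, since its untreated level lay under the background of the treated arrays, with a median of 0.03 (limma camera adjusted p = 0.759). EGR1, an immediate early transcription factor, fell (-1.27, SE 0.21) adjusted over its list of 28 genes alone, and FOSL1 was at 0.74 (SE 0.21), with a list median of 0.09 and a mean of -0.06 (limma camera adjusted p = 0.971). In the interferon list of 21 genes OAS2 (-0.84, SE 0.19) fell and RIGI, a sensor of viral RNA (1.27, SE 0.31, at least 1.89-fold and below background in both untreated arrays), rose adjusted over the list alone, with a median of -0.09 (limma camera adjusted p = 0.566). RIGI differed by 1.94 in the replicate 1 pair and 0.60 in the replicate 2 pair. In the trended fit 3 heat shock, 2 unfolded protein response, 2 immediate early genes and 1 interferon gene fell, and 1 amino acid response gene rose.

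Housekeeping and metabolic lists did not pass limma camera. The median was 0.02 for 45 cytosolic ribosomal protein genes (adjusted p = 0.156), -0.05 for 31 nuclear genes of oxidative phosphorylation (adjusted p = 0.744), -0.05 for 8 mitochondrially encoded genes (adjusted p = 0.971) and -0.18 for 17 cholesterol synthesis genes (adjusted p = 0.971). For 28 proteasome subunits it was -0.13 (adjusted p = 0.156), and PSMA5 (-0.89, SE 0.19) fell in the trended fit. No member of these 5 lists passed over all rows or when adjusted over the list alone. Markers of other cell types were measured to check the samples. The highest group mean was CD3E (8.57) among T cell, COL1A1 (8.06) among fibroblast and KRT8 (7.07) among epithelial markers. It was HBA1 (6.65) among erythroid, PAX5 (6.01) among mature B cell and CSF1R (5.75) among monocyte markers. The tests compare treated with untreated samples, so they do not tell whether other cells were present. Monocyte and macrophage markers had a median of 0.48 (limma camera adjusted p = 0.0487). LYZ (0.87, SE 0.25) and CD163 (0.79, SE 0.21) passed as higher adjusted over the list alone of 8 genes. Both were below background in each group and had no usable fold. CSF1R was at -0.40 (SE 0.27, above background in 1 of the 2 treated arrays) and S100A9, also below background, at -0.60 (SE 0.26). The T cell (0.10), mature B cell (0.12), erythroid (0.22), fibroblast (0.16) and epithelial (0.12) markers had limma camera adjusted p values of 0.496, 0.587, 0.103, 0.496 and 0.599. Of all markers, 0 passed over all rows in either limma fit.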

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

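Tests of array scaling, of background on the treated arrays, of a shift of dim rows and of a shift of all small RNA rows were chosen after closely related values had been seen, and the trended fit behind 2 of the patterns was adopted after the data had been examined. Poly-A control RNAs, which are added to RNA before labelling, were not part of any comparison. Of these dap, phe and thr were above background in the replicate 1 arrays of both groups, lys in untreated replicate 1 alone, and all 4 were below background in the replicate 2 arrays. The difference, replicate 1 minus replicate 2 arrays on the log2 scale, was 6.66 for dap, 2.69 for lys, 4.12 for phe and 5.60 for thr. Another 5 ERCC rows exceeded background in both replicate 1 arrays and in neither replicate 2 array. The hybridisation controls bioB, bioC, bioD and cre differed by -0.08 to 0.09. The replicate numbers therefore followed a difference in added control RNA that was balanced over the groups.

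Far more protein-coding genes fell than rose in the trended fit, 874 against 71 above background. A constant offset between the arrays would leave the fold changes symmetric around their own median. Among genes more than 1 log2 unit from the median, however, 87.0% lay below it, 368 against 55. Uneven scaling that depends on the signal level need not be symmetric, so this count cannot exclude it. With a second quantile normalization the trended fit called 160 genes as higher and 677 as lower, against 117 and 942 without it. Higher background on the treated arrays would mainly compress dim genes. Of the called genes with an untreated mean of at least 9, 92.2% fell, 307 against 26. That cut used the untreated level alone, which favours falls: DDR2, at 8.11 untreated and 10.09 treated, was left out. The share may therefore be overstated, and it does not by itself exclude a part for background. Genomic span could account for part of the pattern: with genes in 4 equal classes of span, the mean log2 fold change of the longest class minus that of the shortest was -0.27 (permutation p = 1e-05, two-sided, the smallest the resamples can give), and within 4 classes of untreated level the difference was -0.31, -0.30, -0.20 and -0.20. That permutation treats genes measured on the same arrays as independent, so its p does not measure the spread between samples. A direct effect of meayamicin B on spliced or elongating transcripts, which would weigh on long genes, and a probe effect that follows gene length both stay open.

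Some genes below background before treatment rose, among them CMYA5, FGF18 and RRH, whose nearest expressed genes TENT2, NPM1 and GAR1 lie 1.59, 8.75 and 3.24 kb away (GRCh38.p14). ERMN, HAVCR1 and TAF7L were also called as higher in the trended fit, with the nearest expressed gene 86.9, 68.0 and 52.6 kb away. HAVCR1 and TAF7L were below background in every array and have no usable fold. The median over 6262 protein-coding genes below background was 0.0393. RMA equalises the array distributions and most rows lay below background, so a general shift of dim rows would largely be removed. That median therefore cannot decide whether such a shift occurred. Transcription reaching in from an expressed neighbour may contribute, but the mean with such a neighbour within 50 kb exceeded that without by 0.0145 (permutation p = 0.0702, two-sided), which leaves it open. In an additional count, 20 of 2976 genes with a neighbour and 5 of 2764 without rose by more than 1 log2 unit (Fisher's exact p = 0.00461), but falls of that size were likewise 7 against 2. The trended calls gave 9 rises against 3 (Fisher's exact p = 0.149). Among the 9, CDO1, CCDC81 and DBNDD2 were likewise below background in every array. The permutation and Fisher's tests treat genes as independent.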

How the results depend on the processing

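The trended fit's alternatives and camera with an intensity trend were chosen after the data had been examined. The cause of each difference was not tested except where fewer arrays or rows explain it. The default count of 22 rows was 1589 with the trended prior, 37 with ribosomal centring, 3 with the filter on dim rows and 0 to 0 when any array was left out, which leaves 1 residual degree of freedom. The count of 11 genes was likewise 1059, 19, 2 and 0 to 0, and the replicate block gave 29 rows and 11 genes, 10 of them shared, with MIPEPP1 (adjusted p = 0.0507) replaced by TECTA (adjusted p = 0.0469) in limma. The same-numbered arrays share only a number in the labels, and with the block NF-kB targets became a 6th list (adjusted p = 0.0460) while no other list call changed. The trended count of 1059 genes was 2168 with the replicate block, 577 with a 2-fold minimum, 837 with quantile normalization (160 higher, 677 lower), 809 with ribosomal centring (96 higher, 713 lower) and 276 to 848 when 1 array was left out, where the lone array is assumed to vary like the other group. The family count of 1 BCL2 gene was 2 with the trended prior. The 5 lists passed under every scaling, filter, block and leave-one-out alternative, but 0 passed with an estimated correlation, 6 passed fry (DNA replication and histones of the 5, with heat shock, NF-kB, plasma cell and intronless genes), and 13 passed camera with an intensity trend. Of the single genes, 8 values changed sign, all below the threshold: BCL2L2 was 0.0078 with quantile normalization. With 1 array left out, it ranged from -0.31 to 0.19, BOK from -0.69 to 0.25, BIK from -0.066 to 0.33, HRK from -0.18 to 0.48, CCNE1 from -0.021 to 0.17 and CDT1 from -0.078 to 0.26. Between 19.7% and 25.6% of rows exceeded background, which limits what can be said of dim genes.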

Other observations

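The test of a shift of all small RNA rows and Fisher's tests of small RNA calls were chosen after closely related values had been seen. So were the comparisons of means with small RNA genes in no gene, the genes named in the next paragraph and the comparison with random lists. The other test in this part was written before its result was seen.

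Several transcripts outside the fixed lists rose in the trended fit. The SEs given for them are from the default fit, in which DDR2, CTNND1, SNORD19 and SNORD69 did not pass. DDR2, a collagen receptor kinase, rose 3.92-fold from 8.11 ± 0.05 to 10.09 ± 0.18 (SD, n = 2 arrays per group, log2 fold change 1.97, SE 0.20), and CTNND1, which encodes p120 catenin, rose 4.59-fold (2.20, SE 0.25) and was above background in 1 of the 2 untreated arrays. The small nucleolar RNA genes SNORD19 (1.68, SE 0.19) and SNORD69 (1.22, SE 0.18) rose as well. Their row identifiers name the same chromosome and are close in number, so these 2 rises may not be independent. Of 302 mitochondrial pseudogenes measured, 3 were called as higher. The identifiers of their rows name the same chromosome and are close in number, so the 3 may not be independent. MTND2P12 was at least 5.62-fold higher and MTND1P14, above background in 1 of the 2 untreated arrays, 10.4-fold higher, but MTCO1P39 was below background in all 4 arrays and has no usable fold, while the median of all 302 was 0.02 and the mitochondrially encoded ND1 and ND2 were at -0.11 and -0.12, neither past the threshold.

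The 5 lists that passed camera were set against 10000 random lists of genes above background, matched on 5 classes of genomic span and 5 of untreated level. Having passed camera on the same fold changes, they were likely to rank as extreme, so the ranks are no separate evidence. The comparison asks only whether span and level, as classed, could give such medians. Lists that did not pass camera were not compared in this way. The median of DNA replication genes, -0.59, lay at or below that of all but 1 random list, whose central 95% ran from -0.37 to 0.00. Homologous recombination genes (-0.67) were matched or passed by 4 random lists. The 30 histone genes above background (-0.43) were matched by 0, and 0 random lists were as high as the 21 p53 targets (0.40) or the 26 KRAB zinc finger genes (0.29) above background. These shares describe the 4 arrays and treat genes as independent. Histone genes had a median span of 0.495 kb, against 5.74 kb in the shortest of 4 span classes of protein-coding genes above background. Their span was therefore matched only loosely, and their result does not set them apart from comparably short genes.

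Small RNA genes lying inside expressed protein-coding genes might be expected to rise if unspliced or intronic host RNA accumulated. The mean log2 fold change of those inside an expressed host exceeded that of those inside a host below background by 0.0126 (permutation p = 0.629, two-sided). The trended fit called 10 of 626 genes as higher inside an expressed host, 0 of 212 inside a host below background (Fisher's exact p = 0.0734, two-sided), 2 of 108 inside a host not measured, and 0 of 682 in no protein-coding gene (Fisher's exact p = 0.000607 against an expressed host). Above background the rises were 9 of 213 inside an expressed host, 0 of 35 inside a host below background (Fisher's exact p = 0.367) and 0 of 160 in no gene (Fisher's exact p = 0.0119 against an expressed host). Over all rows the medians were 0.09 inside an expressed host and 0.0683 in no gene, and above background 0.18 and 0.19. Neither the means nor the calls separated expressed hosts from hosts below background, the comparison written beforehand for host RNA. The calls did differ from those of small RNA genes in no gene, in tests that treat genes as independent. The means did not: expressed hosts were higher by 0.0249 (permutation p = 0.159, two-sided), and above background by 0.0644 (permutation p = 0.104, two-sided). Host RNA and a shift of all small RNA rows both stay open.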
